A study of Homo sapiens with 30 samples.

How the data were processed

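Messenger RNA levels were measured by RNA sequencing in 30 libraries from 3 human breast cancer lines: the luminal MCF-7 and T-47D, and the basal MDA-MB-231. Libraries were prepared with an Illumina TruSeq RNA kit, per the labels. The labels name Trizol for RNA extraction and the series' design text a column kit, so the extraction of a given library was not settled. The authors deposited 1 table per library with unnormalized read counts per gene symbol, as HTSeq writes them. Alignment with STAR, counting with HTSeq 0.6.1 and the genome build GRCh38.p2 come from the submitters' processing notes, which also list SAMtools, Picard and DESeq2 without a role. The gene annotation, the strand setting, the overlap mode of the counting and the STAR version are not given in the sources used here. The tables of the 24 siRNA, DMSO and SR2211 libraries list 58387 names and those of the 6 vector libraries 56638, with 52114 shared (52391 after older symbols were mapped). Reads assigned to more than 1 gene made up 1.79% to 2.05% of reads in the vector libraries and 2.95% to 6.32% in the others, so the vector libraries were counted against another gene list. Their gene changes were tested among themselves, and they were set beside the others in the comparison of control groups (RORC, markers and shared gene names) and in the alternative with all 30 libraries in 1 fit.

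HTSeq's special lines name no gene and were kept out of library sizes and tests. Reads outside annotated genes made up 8.76% to 15.3% of assignable reads in the siRNA libraries, 14.7% to 19.9% with the empty vector, 12.6% to 13.5% with the RORC vector, 26.3% to 30.4% with DMSO and 29.8% to 39.7% with SR2211. Depth was taken as the sum of reads over genes and ranged from 9.29 M to 55.8 M (megareads); CPM is reads per megaread, so at 10 M a level of 1 CPM is 10 reads. The 30 pairs of replicates within groups differed by more than sampling noise (chi-square per degree of freedom 1.63 to 71.6), so each library was counted once. No columns of other series were present.

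Groups were taken from the labels. Each of the 5 comparisons (RORC siRNA against control siRNA in each of 3 lines, RORC vector against empty vector, and SR2211 against DMSO) was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr with a minimum count of 10, robust quasi-likelihood fits and two-sided quasi-likelihood F tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. SE is the size of the log2 fold change divided by the square root of F. The mean over 3 lines and the differences between lines were tested in 1 fit of the 18 siRNA libraries, and the difference between depletion and SR2211 in 1 fit of 12 libraries. RORC levels are CPM after TMM scaling of all 30 libraries. Overlaps of calls were counted among genes tested in both comparisons, against n1 × n2 / N expected by chance and with two-sided Fisher tests, which describe these genes only. No 2 of the 5 comparisons share control libraries.

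Gene groups were 25 lists fixed before the data were examined: TGF-beta response; mesenchymal; epithelial; basal and mammary stem cell; oestrogen receptor and luminal; ROR and circadian clock; homologous recombination and Fanconi DNA repair; DNA replication; mitosis; cholesterol synthesis; fatty acid synthesis; type I interferon; NF-kappaB and inflammatory cytokines; Th17 and RORγt cytokines; ATF4 amino acid stress; unfolded protein response; p53 targets; hypoxia and glycolysis; NRF2 and xenobiotic response; immediate early response; cytosolic ribosomal proteins; oxidative phosphorylation; mitochondrially encoded mRNA; immune cell markers; fibroblast and endothelial markers. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera compares a list with all other genes; fry, tried beside it, asks whether the genes of a list move on balance one way and compares them with no other genes. The 2 lists of immune and of fibroblast and endothelial markers had too few tested members in the luminal siRNA and SR2211 comparisons. Median, mean and test differed in sign for 10 lists, none of them called (lowest adjusted p 0.102). The named genes of each comparison were set by a rule fixed before the data were examined: RORC; the 6 highest and 6 lowest log2 fold changes among called genes with mean CPM of at least 5 and all 3 treated libraries on one side of all 3 controls, pseudogenes left out; and up to 3 called members with the smallest p for the 6 lists with the smallest camera p, with up to 1 for other lists. Joint tests and overlaps used the 4 highest and 4 lowest without the condition on sides. For joint tests, genes of at least 5 CPM in each of the lines or experiments compared were also ranked, which was chosen after values were seen.

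The alternatives were set before the data were examined: RLE size factors, no filter on low counts, a stricter filter (CPM of at least 1 in at least 3 libraries), DESeq2 1.42.0, replicate number as a block, all 30 libraries in 1 fit, each library left out in turn, an estimated correlation or fry for lists, and stricter thresholds for overlaps. Fits without MALAT1 and NEAT1 and a mean over T-47D and MDA-MB-231 only were added after the data were seen. For the seed test, every 7-base word in 3′ UTRs of at least 50 bases (GENCODE transcripts) was scored by whether genes carrying it differed in fold change from the rest.

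The steps were first tested on simulated data with known changes. In these 200 genes were changed, as many up as down, far fewer than were called in the real comparisons. Scaling under broad change was thus not tested. At 1.5-fold, 2-fold and 4-fold, the fit of the libraries labelled MCF-7 found 70.1%, 91.0% and 98.5% of changed genes (15630 genes tested, 9.90% of calls false) and that of T-47D 85.1%, 92.5% and 100% (15766 genes, 8.87% false). For MDA-MB-231 siRNA the shares were 92.5%, 98.5% and 100% (18344 genes, 8.92% false), for the vector 86.6%, 97.0% and 100% (16149 genes, 5.50% false) and for SR2211 77.6%, 89.4% and 100% (15060 genes, 6.35% false). In every fit the false share of calls lay above the level of 0.05 set for adjusted p. The seed test found 5 of 5 planted words. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6.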

Results

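RORC encodes RORγ, a nuclear receptor and transcription factor of the retinoic acid-related orphan receptor family. RNA was sequenced from breast cancer cell lines in which RORC was depleted by small interfering RNA (siRNA), supplied from an expression vector, or blocked with a compound. MCF-7 and T-47D are luminal lines that carry the oestrogen receptor, and MDA-MB-231 is a basal line that lacks it. The 30 libraries formed 10 groups of 3. In each of the 3 lines a control siRNA was compared with RORC siRNA after 48 h. MDA-MB-231 cells with an empty vector were compared with cells carrying a RORC vector after 48 h, and MCF-7 cells in the solvent DMSO were compared with cells in 5 µM SR2211, an antagonist of RORγ, after 24 h. Reads counted in genes, given here in megareads (M), ranged from 9.29 M to 55.8 M per library. The MDA-MB-231 siRNA libraries were the deepest, with 47.1 M to 55.8 M, and the 18 MCF-7 and T-47D libraries held 9.29 M to 17.7 M. The 6 vector libraries held 17.4 M to 26.4 M. No label says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Fold changes are given as log2 fold change ± SE of treated over control, from 3 libraries per group.

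The targeted gene was examined first in every group. RORC stood at 53.9 ± 2.62 CPM (reads per megaread in genes, mean ± SD, n = 3) in the control siRNA libraries labelled MCF-7 and at 5.12 ± 0.638 with RORC siRNA. By the fit of these 6 libraries, which has its own scaling, 9.37% of the control level was left (-3.42 ± 0.0969). T-47D went from 46.2 ± 0.973 to 4.07 ± 0.216 CPM, and its own fit put the level at 8.60% of control (-3.54 ± 0.0933). MDA-MB-231 held little RORC to begin with, at 0.610 ± 0.223 CPM from 20 to 37 reads per library. RORC siRNA lowered it to 0.127 ± 0.0423 CPM from 5 to 9 reads (-2.24 ± 0.363). By edgeR's quasi-likelihood test the Benjamini-Hochberg adjusted p was 9.2e-22, 9.1e-26 and 0.00012 in these 3 comparisons. The empty-vector libraries held no RORC reads and the RORC vector libraries 219 ± 14.5 CPM. MDA-MB-231 with control siRNA had held 0.610 CPM, and why these controls differed was not tested. Scaled within the 6 vector libraries, 3 reads over the empty-vector group equal 0.0448 CPM, so RORC was at least 4751-fold higher with the vector (12.21 on the log2 scale, and 11.47 without empty vector replicate 1). This floor covers counting error only, as do all read limits here. SR2211 raised the RORC transcript from 6.18 ± 0.664 to 24.9 ± 1.14 CPM. By its own fit this was a 4.07-fold rise (2.02 ± 0.105, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 9.1e-10). RORC lies on the minus strand of chromosome 1 at 151806071 to 151831872 of GRCh38 (GENCODE annotation), and its 3′ end overlaps LINGO4 (151800264 to 151806154) on the same strand, so how reads there were assigned is uncertain.

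**Figure D1:**
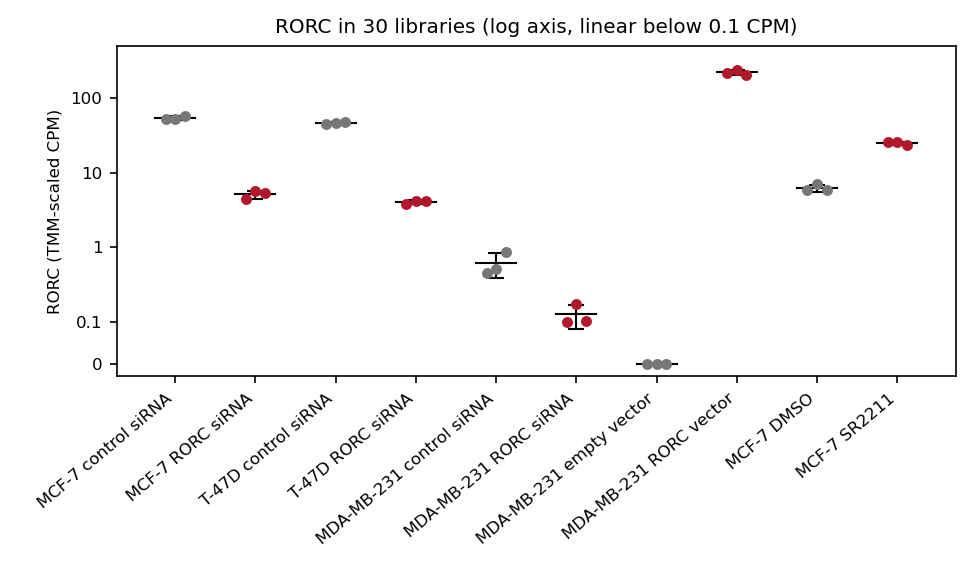
RORC level in CPM on a log axis for each of the 30 libraries, with the group mean and SD. By the separate fit of each comparison, the siRNA groups fell to 9.37%, 8.60% and 21.1% of control. The RORC vector group stood at 219 CPM, and the 3 empty-vector libraries held no reads.

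Control groups differed in RORC level and in marker genes. RORC was 88.3-fold higher in the control siRNA libraries labelled MCF-7, and 75.7-fold higher in those of T-47D, than in MDA-MB-231, and 8.72-fold and 7.48-fold higher than in MCF-7 with DMSO. Each of the 10 two-sided exact permutation tests between control groups gave p = 0.1, the smallest that 3 against 3 can give (0.1 after Benjamini-Hochberg adjustment). MTAP, a methionine salvage enzyme, stood at 28.9 ± 1.20 CPM in the control siRNA libraries labelled MCF-7, 24.7 ± 1.43 in T-47D and 1.07 ± 0.0792 in MCF-7 with DMSO. The phosphatase gene PPM1D stood at 20.2 ± 2.11, 18.7 ± 0.297 and 391 ± 3.32 CPM in the same order. BCAS3, which lies near PPM1D in the genome, stood at 29.7 ± 0.700, 30.1 ± 1.95 and 526 ± 17.1. ESR1, the oestrogen receptor, stood at 349 ± 7.19, 351 ± 12.6 and 457 ± 15.0 CPM. These markers were chosen after values of the libraries were seen. The siRNA libraries labelled MCF-7 thus lay close to T-47D in these markers, and they are called "labelled MCF-7" throughout.

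**Figure D2:**
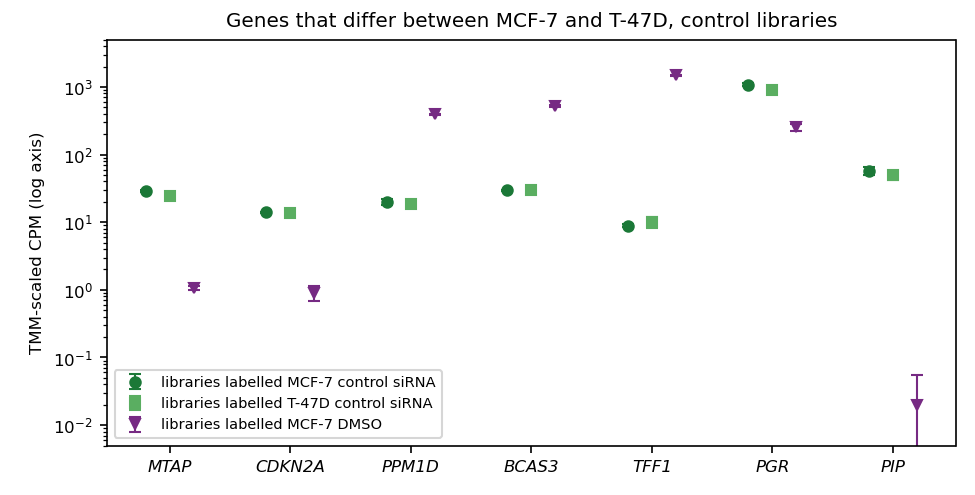
Levels of marker genes in CPM on a log axis in the control siRNA groups labelled MCF-7 and T-47D and in MCF-7 with DMSO, as means of 3 libraries with SD. In the siRNA experiment the libraries labelled MCF-7 and T-47D lie together, while MCF-7 with DMSO has far less MTAP, CDKN2A and PIP and far more PPM1D, BCAS3 and TFF1.

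The first siRNA comparison asked which genes change when RORC is depleted in the luminal libraries labelled MCF-7. Cell-cycle genes fell and amino acid stress genes rose. All but 1 of the 32 tested mitosis genes fell, among them the spindle regulators DLGAP5 (-1.49 ± 0.0487) and KIF2C (-1.45 ± 0.0478) and the mitotic kinase CDK1 (-1.36 ± 0.0459). The median of the list was -0.89 (camera, Benjamini-Hochberg adjusted p = 4.7e-49, and adjusted p = 0.0402 with an estimated correlation). Of 33 DNA replication genes 30 fell, 31 when adjusted over the list alone, with PCNA, the sliding clamp of DNA polymerase, at -1.89 ± 0.0516, the replication initiator MCM10 at -1.68 ± 0.0642 and the helicase subunit MCM4 at -1.14 ± 0.0436 (median -1.07, camera, Benjamini-Hochberg adjusted p = 2.2e-46, and adjusted p = 0.0333 with an estimated correlation). Homologous recombination and Fanconi genes fell in 26 of 33 cases and rose in 2 (27 and 2 adjusted over the list alone; median -0.86, camera, Benjamini-Hochberg adjusted p = 1.6e-17, and adjusted p = 0.0402 with an estimated correlation). Among them were BRCA1 (-1.44 ± 0.0628), the Fanconi pathway protein FANCD2 (-1.13 ± 0.0542) and the resection nuclease EXO1 (-1.58 ± 0.0828). Of 27 ATF4 amino acid stress genes 21 rose and 4 fell (median 0.59, camera, Benjamini-Hochberg adjusted p = 1.7e-17, and adjusted p = 0.0402 with an estimated correlation), among them DDIT4, an inhibitor of mTOR signalling, at 2.13 ± 0.0599, the pseudokinase TRIB3 at 1.17 ± 0.0445 and the stress transcription factor DDIT3 at 1.21 ± 0.0521. Where only a single count is given for a list here and in what follows, the count adjusted over the list alone was the same.

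Single genes moved further. The highest rises were in MET, the hepatocyte growth factor receptor (3.19 ± 0.187), the neuronal adhesion molecule NRCAM (2.63 ± 0.137), SSPO (2.28 ± 0.222), LRRC31 (2.24 ± 0.171), the serine protease inhibitor SERPINI1 (2.18 ± 0.0989) and the guidance factor NTN1 (2.17 ± 0.0661). Lowest were the aggrecan-cleaving protease ADAMTS4 (-3.12 ± 0.0854), the membrane protein TMEM64 (-2.97 ± 0.120), OIP5, which helps load the centromeric histone CENP-A (-2.71 ± 0.123), CBFB, the partner of RUNX transcription factors (-2.47 ± 0.0831), the transcriptional repressor E2F7 (-2.47 ± 0.103) and the mRNA decapping enzyme DCP2 (-2.32 ± 0.0567). Cholesterol synthesis genes fell in 19 of 25 cases and rose in 2 (4 adjusted over the list alone; median -0.35, camera, Benjamini-Hochberg adjusted p = 0.00011, and adjusted p = 0.0625 with an estimated correlation), including the sterol carrier STARD4 (-1.39 ± 0.0863), MSMO1 (-0.71 ± 0.0541) and HMGCS1 (-0.64 ± 0.0536). TGF-beta response genes rose in 15 of 24 cases and fell in 3 (median 0.45, camera, Benjamini-Hochberg adjusted p = 0.00014, and adjusted p = 0.0469 with an estimated correlation). LTBP1, which stores latent TGF-beta, rose by 0.88 ± 0.0461 and the matrix protein THBS1 by 1.23 ± 0.0652, while the receptor TGFBR1 fell by 0.82 ± 0.0488. Weaker calls covered mesenchymal genes (10 of 18 rose and none fell, 1 adjusted over the list alone; median 0.42), oestrogen receptor and luminal genes (16 of 30 rose and 8 fell, 9 adjusted over the list alone; median 0.24), basal and mammary stem cell genes (9 of 16 rose and 1 fell; median 0.35) and oxidative phosphorylation (19 of 32 fell and 2 rose; median -0.18). Their Benjamini-Hochberg adjusted camera p was 0.024, 0.041, 0.047 and 0.013, against adjusted p = 0.17, 0.37, 0.19 and 0.45 with an estimated correlation. The luminal call was lost without control replicate 1 or 3 (adjusted p = 0.0631 and 0.0628) and the basal call without control replicate 3 or RORC siRNA replicate 3 (0.0556 and 0.0536) or with the stricter filter (0.0533). The other 13 lists tested were not called (adjusted camera p 0.0848 to 0.876, medians -0.24 to 0.50).

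In all, 8176 of 16012 tested genes changed, 4228 up and 3948 down (3491 and 4180 with no filter on low counts), of which 612 rose and 498 fell at least 2-fold. Adjusted p for the 30 named genes ran from 6.6e-22 to 4.4e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. RORC siRNA replicate 2 stood apart in the mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2, which took 6.23% of its reads in genes against 0.0226% to 0.0704% in the other siRNA libraries; without it 7943 genes were called.

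In the libraries labelled T-47D the same question was asked, and cell-cycle genes again fell while amino acid stress genes rose. All 32 mitosis genes fell (median -1.35, camera, Benjamini-Hochberg adjusted p = 1.1e-59, and adjusted p = 0.0595 with an estimated correlation), with KIF2C at -1.92 ± 0.0552, DLGAP5 at -1.94 ± 0.0584 and CDK1 at -1.69 ± 0.0582. All 33 DNA replication genes fell (median -1.59, camera, Benjamini-Hochberg adjusted p = 6.2e-54, and adjusted p = 0.0491 with an estimated correlation), among them PCNA (-2.58 ± 0.0584), the licensing factor CDC6 (-2.47 ± 0.0731) and MCM10 (-2.23 ± 0.0667). Of 33 homologous recombination and Fanconi genes 27 fell and 1 rose (median -1.41, camera, Benjamini-Hochberg adjusted p = 3.8e-22, and adjusted p = 0.0491 with an estimated correlation), with BRCA1 at -1.88 ± 0.0610 and the nuclease MRE11A at -1.50 ± 0.0589. ATF4 stress genes rose in 24 of 27 cases and fell in 1 (median 1.11, camera, Benjamini-Hochberg adjusted p = 3.6e-24, but adjusted p = 0.27 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, rose by 3.22 ± 0.143 and the glycyl-tRNA synthetase GARS by 1.78 ± 0.0594.

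The highest rises in T-47D were in UNC5B, a netrin receptor (4.29 ± 0.203), GDF15, a stress-induced cytokine of the TGF-beta family (4.05 ± 0.274), the transporter ABCC12 (3.95 ± 0.225), the chloride channel BEST1 (3.86 ± 0.201), LRRC31 (3.72 ± 0.150) and the inhibin subunit INHBE (3.44 ± 0.0996). ADAMTS4 (-3.90 ± 0.103), OIP5 (-3.72 ± 0.134), TMEM64 (-3.30 ± 0.105), E2F7 (-3.16 ± 0.0984), the glycoprotein LRG1 (-2.86 ± 0.119) and the receptor GPR63 (-2.64 ± 0.166) fell the most. Metabolic groups fell as well. Cholesterol synthesis genes fell in 20 of 25 cases and rose in 2 (median -0.64, camera, Benjamini-Hochberg adjusted p = 7.9e-06, but adjusted p = 0.47 with an estimated correlation), with the mevalonate enzymes HMGCS1 at -0.92 ± 0.0561, MVK at -1.09 ± 0.0660 and MVD at -0.91 ± 0.0620. Oxidative phosphorylation genes fell in 27 of 32 cases and rose in 1 (median -0.37, camera, Benjamini-Hochberg adjusted p = 2.2e-05, but adjusted p = 0.52 with an estimated correlation), with cytochrome c (CYCS) at -1.16 ± 0.0535 and the complex I subunit NDUFS1 at -0.76 ± 0.0527. Fatty acid synthesis genes fell in 14 of 21 cases and rose in 2 (median -0.33), including the desaturase FADS1 (-1.19 ± 0.0632). Rising groups were the TGF-beta response (12 of 24 up, 13 adjusted over the list alone, and 4 down; median 0.35), the unfolded protein response of the endoplasmic reticulum (13 of 23 up and 5 down, 7 adjusted over the list alone; median 0.19), the type I interferon response (19 of 30 up and 5 down; median 0.47) and mesenchymal genes (10 of 17 up, 11 adjusted over the list alone, and 4 down; median 0.44). Examples were ID1, a target of BMP and TGF-beta signalling (1.67 ± 0.0784), the stress protein HERPUD1 (1.90 ± 0.0668) and the collagen COL5A1 (2.17 ± 0.146). For fatty acid synthesis and these 4 groups the Benjamini-Hochberg adjusted camera p was 0.012, 0.0041, 0.017, 0.031 and 0.031, against adjusted p = 0.52, 0.34, 0.54, 0.64 and 0.27 with an estimated correlation. The interferon call was lost without RORC siRNA replicate 3 (adjusted p = 0.0606). The other 12 lists tested were not called (adjusted camera p 0.107 to 0.966, medians -0.28 to 0.19). In all, 9947 of 16270 tested genes changed, 4982 up and 4965 down, with 1001 up and 1015 down at least 2-fold. The 30 named genes had adjusted p from 3.1e-27 to 4.1e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

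MDA-MB-231, the basal line with little RORC, received the same siRNA. Inflammatory and interferon genes fell here along with DNA repair genes. None of 25 NF-kappaB and cytokine genes rose by edgeR's test and 17 fell, such as the signalling adaptor TRAF1 (-1.38 ± 0.0603), the cytokine LIF (-0.76 ± 0.0476) and TNFAIP2 (-0.43 ± 0.0454), with a list median of -0.73. Of 33 type I interferon genes 24 fell and 4 rose (median -0.41), among them SAMD9 (-0.83 ± 0.0442), IFIT3 (-0.53 ± 0.0336) and the ISG15 ligase HERC5 (-0.50 ± 0.0337). Homologous recombination and Fanconi genes fell in 26 of 33 cases and rose in 1 (27 and 2 adjusted over the list alone; median -0.35), with MRE11A at -0.94 ± 0.0325, BRCA1 at -0.75 ± 0.0466 and the recombinase RAD51 at -0.61 ± 0.0465. DNA replication genes fell in 22 of 33 cases and rose in 4 (median -0.26), with PCNA at -1.28 ± 0.0598, GINS1 at -0.77 ± 0.0445 and MCM7 at -0.46 ± 0.0426. The Benjamini-Hochberg adjusted camera p of these 4 lists was 3.7e-05, 2.7e-05, 7.8e-06 and 0.0012, and each had adjusted p = 0.97 with an estimated correlation.

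The highest single rises in MDA-MB-231 were in the epithelial surface antigen TACSTD2 (1.90 ± 0.0402), the mitochondrial phosphatase PTPMT1 (1.88 ± 0.0652), the lysosomal amino acid transporter SLC36A1 (1.82 ± 0.0651), the oxytocin receptor OXTR (1.75 ± 0.0835), the tyrosine phosphatase PTPN1 (1.68 ± 0.0338) and WSB1 (1.62 ± 0.0391). The growth factor CSF2 fell the furthest (-3.17 ± 0.301), followed by CBFB (-2.74 ± 0.0468), TMEM64 (-2.49 ± 0.0435), OIP5 (-2.48 ± 0.0642), the glycolipid enzyme B4GALT6 (-2.43 ± 0.0741) and the T-cell costimulatory receptor TNFRSF9 (-2.15 ± 0.206). Genes of the oestrogen receptor and luminal list fell in 10 of 20 cases (11 adjusted over the list alone) and rose in 2 (median -0.28), including the cyclin CCND1 (-1.26 ± 0.0447), the ubiquitin ligase SIAH2 (-0.95 ± 0.0455) and SPDEF (-0.76 ± 0.0548). Mitochondrially encoded mRNAs rose in 10 of 13 cases (12 adjusted over the list alone, median 0.46), as in MT-ND2 (0.39 ± 0.0659), MT-ND5 (0.44 ± 0.0708) and MT-ND4L (0.36 ± 0.0687). Mitochondrial ribosomal RNA made up 0.02255% to 0.02654% of reads in genes with control siRNA and 0.02805% to 0.03139% with RORC siRNA. Mitosis genes fell in 18 of 32 cases and rose in 5 (median -0.12), and immediate early genes fell in 13 of 26 and rose in 4 (median -0.28). ATF4 stress genes rose in 15 of 27 cases and fell in 2 (median 0.22), and NRF2 and xenobiotic genes rose in 14 of 25 and fell in 5 (median 0.215). Adjusted camera p for these 6 lists was 0.013, 0.016, 0.019, 0.037, 0.019 and 0.042 after Benjamini-Hochberg adjustment; with an estimated correlation it was adjusted p = 0.76 for the luminal list and 0.97 for the other 5. Calls were lost for mitochondrial mRNA and mitosis without RORC siRNA replicate 2 (adjusted p = 0.108 and 0.0777), for immediate early genes without control replicate 1 or 3 or RORC siRNA replicate 1 (0.0521 to 0.0616), and for NRF2 genes without control replicate 1 or 2 (0.0513 and 0.0614). The stricter filter ended the mitosis, immediate early and NRF2 calls (0.0547 to 0.0779). MT-ND2, MT-ND5 and MT-ND4L were not called in 1 fit of all 30 libraries. The other 15 lists were not called (adjusted camera p 0.0506 to 0.942, medians -0.13 to 0.23). In all, 9225 of 18704 tested genes changed, 4518 up and 4707 down, but only 310 rose and 280 fell at least 2-fold. Adjusted p of the 30 named genes lay between 3.1e-14 and 0.00071 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

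**Figure D3:**
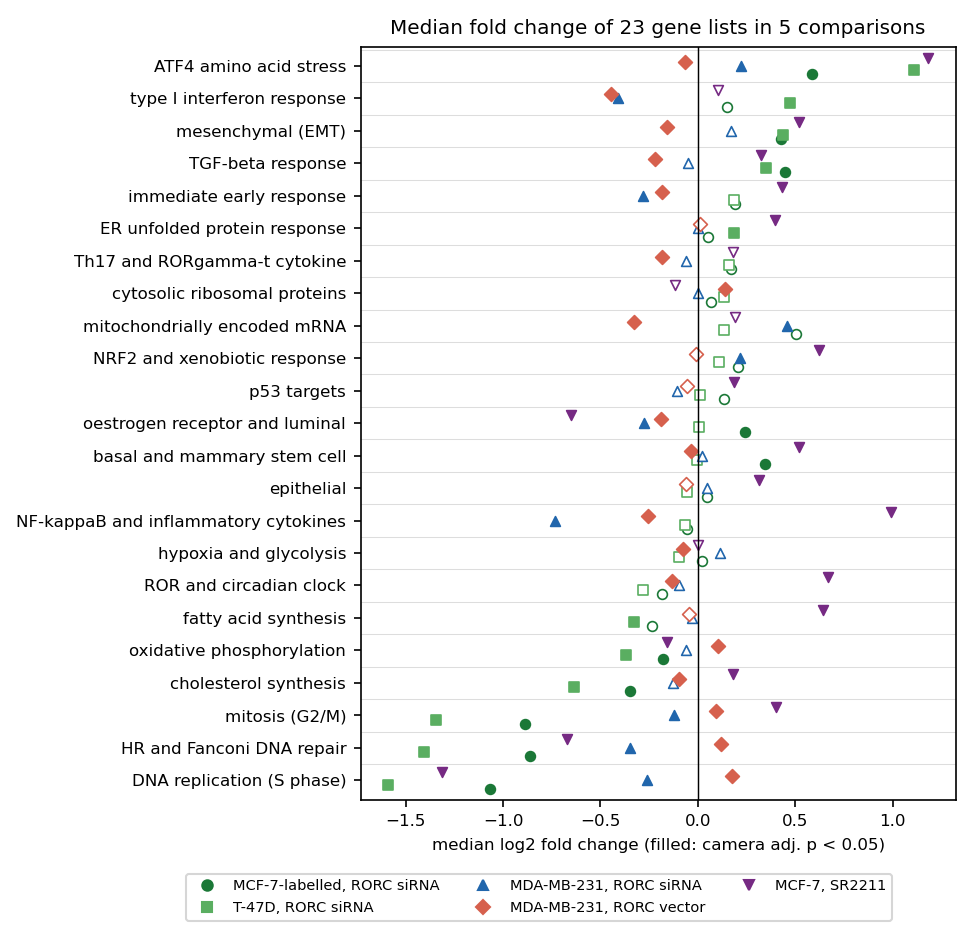
Median log2 fold change of the tested members of each fixed gene list (one line of points per list) in the 5 comparisons, with lists called by camera at a Benjamini-Hochberg adjusted p under 0.05 marked. DNA replication genes have medians of -1.07, -1.59, -0.26 and -1.31 with the RORC siRNAs and SR2211, and of 0.17 with the RORC vector.

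Averaged over the 3 siRNA experiments in 1 fit of 18 libraries, 10962 of 18611 genes changed, 5779 up and 5183 down (5156 and 5651 with no filter on low counts). RORC fell by 3.05 ± 0.119 on the log2 scale, OIP5 by 2.96 ± 0.0626, TMEM64 by 2.91 ± 0.0528 and CBFB by 2.52 ± 0.0393. Among genes of at least 5 CPM in each line, a filter chosen after values were seen, the tight junction gene CLDN1 rose by 2.15 ± 0.0610 and GDF15 by 2.0 ± 0.164, and DCP2 fell by 2.18 ± 0.0302. The mean of GDF15 hid a difference between lines, since it rose by 2.06 ± 0.302 and 4.07 ± 0.314 in the luminal libraries and stood at -0.11 ± 0.197 in MDA-MB-231. There GDF15 had 589, 592 and 629 reads with control siRNA and 496, 880 and 481 with RORC siRNA, so replicate 2 raised the value. That library differed more from RORC siRNA replicates 1 and 3 (chi-square per degree of freedom 8.78 and 8.36) than those did from each other (2.23). MT-RNR1 was 2.63 ± 0.847 in the mean but 0.48 without RORC siRNA replicate 2 labelled MCF-7, whose reads set the value. LRRC31, RCSD1, MARCKS and CFH also ranked among the 8 furthest genes, but each had 3 reads or fewer in a group of 3 libraries.

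Genes moved together across the 3 siRNA sets. Libraries labelled MCF-7 and T-47D shared 7086 calls, of which 99.5% went the same way (Pearson r = 0.870 across genes, which are not independent replicates). Both luminal sets lay close in marker genes and may come from the same line, so their agreement may not be agreement between lines. With MDA-MB-231 the shares were 86.4% of 5124 genes for the libraries labelled MCF-7 (r = 0.531) and 82.2% of 5824 for T-47D (r = 0.493). Called in all 3 sets were 4602 of 14481 genes: 1848 rose in each (308 by chance), 2168 fell in each (349 by chance) and 586 were mixed. The chance counts take the sets as independent of one another. CLDN1, PTPMT1, the water channel AQP3 and the haem oxygenase HMOX1 rose the most in T-47D and MDA-MB-231 together. OIP5, TMEM64, CBFB and DCP2 fell the most.

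Tests of the difference between siRNA sets called 1672 genes between libraries labelled MCF-7 and T-47D (1028 higher and 644 lower in the former, but 801 and 925 with no filter on low counts), 5059 between those labelled MCF-7 and MDA-MB-231 (2291 and 2768) and 7015 between T-47D and MDA-MB-231 (3302 and 3713). The fall of RORC did not pass as different between the 2 luminal sets (0.10 ± 0.166, edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.81) and was deeper than in MDA-MB-231 by 1.21 ± 0.419 in the libraries labelled MCF-7 and by 1.31 ± 0.420 in T-47D. These last differences were lost without MDA-MB-231 RORC siRNA replicate 2 (edgeR, Benjamini-Hochberg adjusted p = 0.25 and 0.16), and the former also without MDA-MB-231 control replicate 1 or 2 (0.0624 and 0.0600). Among genes of at least 5 CPM in both lines compared, the filter chosen after values were seen, UNC5B (-2.29 ± 0.212), GDF15 (-2.01 ± 0.499), LAMP3 (-1.79 ± 0.310) and CHAC1 (-1.56 ± 0.284) rose less in the libraries labelled MCF-7 than in T-47D. The GDF15 difference was lost without control replicate 1 or 3 of either luminal set (edgeR, Benjamini-Hochberg adjusted p = 0.0517 to 0.0763). The transcription factor GATA4 (1.33 ± 0.202), the cytoskeletal linker EPB41L2 (1.31 ± 0.170), CSPG4 (1.18 ± 0.174) and the collagen COL12A1 (1.16 ± 0.136) were lower in T-47D after siRNA relative to the libraries labelled MCF-7. SOX9, a transcription factor of stem and progenitor cells, rose in T-47D relative to MDA-MB-231 by 3.32 ± 0.193, the lectin chaperone CLGN by 3.54 ± 0.224 and FAM129A by 3.46 ± 0.160. E2F7 (-2.40 ± 0.10), the adhesion scaffold NEDD9 (-2.18 ± 0.122), CYTH3 (-2.01 ± 0.0867) and the matrix protein EFEMP1 (-1.97 ± 0.0628) fell in T-47D relative to MDA-MB-231. Under the same filter E2F7, CYTH3, FARP2 and NEDD9 led the falls in the libraries labelled MCF-7 relative to MDA-MB-231, and SOX9 (2.23 ± 0.182) and the EGF-receptor ligand AREG (2.20 ± 0.161) led the rises after MT-RNR1.

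Supplying RORC to MDA-MB-231 asked the reverse question. Interferon, inflammatory and immediate early genes fell with the RORC vector, and genes of DNA replication rose slightly, though no list kept its call with an estimated correlation. Of 31 type I interferon genes 22 fell (24 adjusted over the list alone) and none rose by edgeR's test, with a median of -0.45. IFIT2, IFIT1 and IFIT3, which bind viral RNA, fell by 1.68 ± 0.0387, 1.13 ± 0.0443 and 0.85 ± 0.0356. NF-kappaB and cytokine genes fell in 16 of 26 cases (19 adjusted over the list alone) and rose in 1 (median -0.26), with the prostaglandin synthase PTGS2 at -0.96 ± 0.0528, the NF-kappaB inhibitor TNFAIP3 at -0.97 ± 0.0614 and CSF1 at -0.54 ± 0.0407. Immediate early genes fell in 15 of 27 cases (17 adjusted over the list alone; median -0.19), among them EGR1 (-1.22 ± 0.0919) and ATF3 (-1.06 ± 0.0911). DNA replication genes rose in 24 of 33 cases (26 adjusted over the list alone; median 0.17), with RRM2, the ribonucleotide reductase subunit, at 0.32 ± 0.0408, ORC1 at 0.33 ± 0.0451 and FEN1 at 0.25 ± 0.0353. The Benjamini-Hochberg adjusted camera p of these 4 lists was 2.4e-24, 3.8e-13, 1.3e-08 and 3.8e-13, against adjusted p = 0.0649, 0.0636, 0.0649 and 0.0636 with an estimated correlation.

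The lowest single genes were the heat shock protein HSPA6 (-2.24 ± 0.125), GDF15 (-2.14 ± 0.105), IFIT2, the cholesterol exporter ABCA1 (-1.37 ± 0.0744), DDIT4 (-1.25 ± 0.0461) and EGR1. Rises were small: after RORC itself the highest were the histone gene HIST1H2AA (0.80 ± 0.0775), the lipase inhibitor ANGPTL4 (0.78 ± 0.0999), the small nucleolar RNA SNORD3B-2 (0.71 ± 0.0779), HIST1H2BA (0.63 ± 0.0483), the antisense transcript ZBTB11-AS1 (0.54 ± 0.0933) and HIST1H2BB (0.53 ± 0.0410). Histone and small nucleolar genes have near-identical copies, and the strand setting of the counting was not given, so these 5 values are uncertain. Mitochondrially encoded mRNAs fell in 7 of 13 cases (8 adjusted over the list alone; median -0.33), as in MT-ND4 (-0.43 ± 0.0487). Mitochondrial ribosomal RNA made up 0.0519% to 0.314% of reads in genes with the empty vector and 0.0333% to 0.0405% with the RORC vector. Reads outside genes made up 14.7% to 19.9% and 12.6% to 13.5% of assignable reads. Cytosolic ribosomal protein genes rose in 24 of 35 cases (29 adjusted over the list alone; median 0.14), among them RPL6 (0.25 ± 0.0355) and RPS5 (0.22 ± 0.0361). Homologous recombination genes (14 of 33; median 0.12), oxidative phosphorylation (10 of 32, 13 adjusted over the list alone; median 0.10) and mitosis genes (14 of 32, 15 adjusted over the list alone; median 0.09) also rose, with none falling by edgeR's test. Falling lists included the TGF-beta response (15 of 29 down, 16 adjusted over the list alone, and 4 up; median -0.22), ROR and circadian clock genes (9 of 24 down, 11 adjusted over the list alone, and 1 up; median -0.13), ATF4 stress (12 of 26 down and 2 up, 3 adjusted over the list alone; median -0.07) and cholesterol synthesis (9 of 26 down and 2 up; median -0.10). Mesenchymal genes fell in 9 of 27 cases (13 adjusted over the list alone) and rose in 1 (2 adjusted over the list alone; median -0.16), luminal genes in 8 of 17 (median -0.19), basal genes in 5 of 17 (median -0.03), hypoxia and glycolysis genes in 12 of 32 against 6 that rose (14 and 6 adjusted over the list alone; median -0.08) and Th17 and RORγt cytokine genes in 3 of 9 (4 adjusted over the list alone; median -0.18). The clock repressor BHLHE40 (-1.16 ± 0.0655) and the TGF-beta target KLF10 (-0.58 ± 0.0449) were examples. Adjusted camera p over the 18 called lists ran from 2.4e-24 to 0.0301, and all were lost with an estimated correlation (adjusted p = 0.0636 to 0.241). The Th17 call was also lost without empty vector replicate 2 or RORC vector replicate 1 (0.109 and 0.0617), and MT-ND4 was not called in 1 fit of all 30 libraries. The other 7 lists were not called (adjusted camera p 0.0605 to 0.558, medians -0.40 to 0.01). In all, 3634 of 16348 genes changed, 1866 up and 1768 down, with 10 up and 83 down at least 2-fold, and 2103 were called without empty vector replicate 1. The 30 named places in this comparison went to 28 genes, with adjusted p from 6.5e-17 to 0.00056 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

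Depletion and supply of RORC in MDA-MB-231 were then set against each other. Of 2275 genes called in both, 1490 moved in opposite directions (980 by chance) and 34.5% moved the same way (r = -0.108 across genes). Furthest among those higher after siRNA and lower with the vector were TCP11L2 (1.34 and -1.18), ABCA1 (0.83 and -1.37), WSB1 (1.62 and -0.15) and EPB41L1 (1.4 and -0.35). Those lower after siRNA and higher with the vector were led by CBFB (-2.74 and 0.18), PSMC3IP (-1.73 and 0.19), SFXN1 (-1.61 and 0.16) and the tissue factor gene F3 (-1.60 and 0.15). CBFB, SFXN1 and F3, but not PSMC3IP, carry the 3′ UTR word GCTTCTA. That word is weighed below as a mark of unintended siRNA targets, so these falls may not reflect RORC. CSF2 (-3.17 and -1.02) and IFIT2 (-0.35 and -1.68) fell in both. So did some lists called by camera in both. These were type I interferon (medians -0.41 and -0.45), NF-kappaB (-0.73 and -0.26), immediate early (-0.28 and -0.19) and luminal genes (-0.28 and -0.19). Lists of DNA replication, homologous recombination, mitosis, ATF4 stress and mitochondrial mRNA moved in opposite directions. None of these calls was kept with an estimated correlation. At changes of at least 2-fold 3 shared genes were opposite and 62.5% moved the same way. The small vector changes of WSB1 and PSMC3IP were lost without empty vector replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.18 and 0.0848), and that of WSB1 also without empty vector replicate 3 or RORC vector replicate 1 or 2 (0.12, 0.0730 and 0.15) and with DESeq2 (0.0886).

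SR2211 in MCF-7 asked what blocking RORγ does to gene expression. DNA replication genes all fell and ATF4 stress genes rose. The 33 replication genes had a median of -1.31 (camera, Benjamini-Hochberg adjusted p = 1.1e-51, and adjusted p = 0.0102 with an estimated correlation), with the replisome subunits GINS2 at -2.05 ± 0.0691 and GINS1 at -1.67 ± 0.0575 and MCM4 at -1.45 ± 0.0501. ATF4 stress genes rose in 22 of 26 cases and fell in 2 (median 1.18, camera, Benjamini-Hochberg adjusted p = 2.3e-37, and adjusted p = 0.0102 with an estimated correlation), including the stress regulator NUPR1 (4.31 ± 0.102), DDIT3 (3.78 ± 0.0759) and the cystine transporter SLC7A11 (2.75 ± 0.0755). Oestrogen receptor and luminal genes fell in 23 of 30 cases and rose in 2 (median -0.65, camera, Benjamini-Hochberg adjusted p = 1.3e-13, and adjusted p = 0.0102 with an estimated correlation), with MYB at -1.36 ± 0.0521, the elongase ELOVL2 at -1.75 ± 0.0672 and AREG at -1.55 ± 0.0714. Homologous recombination and Fanconi genes fell in 28 of 33 cases (29 adjusted over the list alone) and rose in 2 (median -0.67, camera, Benjamini-Hochberg adjusted p = 2.0e-13, and adjusted p = 0.0380 with an estimated correlation), with BRCA1 at -1.23 ± 0.0587 and XRCC2 at -1.45 ± 0.0755. Fatty acid synthesis genes rose in 14 of 20 cases and fell in 1 (median 0.64, camera, Benjamini-Hochberg adjusted p = 5.3e-11, and adjusted p = 0.0102 with an estimated correlation), with the acyl-CoA synthetase ACSL1 at 2.91 ± 0.0620, the desaturase SCD at 2.82 ± 0.0610 and their regulator SREBF1 at 1.71 ± 0.0646. NRF2 and xenobiotic genes rose in 15 of 23 cases and fell in 1 (median 0.62, camera, Benjamini-Hochberg adjusted p = 9.9e-08, and adjusted p = 0.0289 with an estimated correlation), with the xenobiotic enzyme CYP1A1 at 3.51 ± 0.188 and the ferritin heavy chain FTH1 at 1.45 ± 0.0526.

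The highest single rises with SR2211 were in the calcium-binding protein S100P (5.63 ± 0.169), the microtubule protein MAP1B (4.34 ± 0.151), NUPR1, the nuclear long noncoding RNA NEAT1 (4.04 ± 0.451), GDF15 (3.91 ± 0.0910) and the potassium channel subunit KCNG1 (3.83 ± 0.242). The BMP regulator BMPER (-3.34 ± 0.136), the chemokine receptor CXCR4 (-3.11 ± 0.165), the cytokine IL20 (-3.06 ± 0.136), FAM111B (-3.0 ± 0.112) and the bicarbonate transporter SLC4A10 (-2.96 ± 0.172) fell the most. U3, a repeated small nucleolar RNA family that could not be placed, stood at -2.70 ± 0.163 and is uncertain. Clock genes rose in 18 of 22 cases and fell in 3 (median 0.67; DBP 1.77 ± 0.0608), immediate early genes rose in 15 of 24 and fell in 5, 6 adjusted over the list alone (median 0.43; KLF6 1.90 ± 0.0656), and mitosis genes rose in 25 of 32 and fell in 3 (median 0.40; CDC20 0.87 ± 0.0524). The unfolded protein response rose in 15 of 23 cases and fell in 3 (median 0.40), p53 targets in 16 of 28 (17 adjusted over the list alone) against 5 that fell (median 0.19), epithelial genes in 18 of 30 against 6 (median 0.32) and mesenchymal genes in 8 of 14 (9 adjusted over the list alone; median 0.52). TGF-beta response genes rose in 17 of 25 cases against 5 that fell, 6 adjusted over the list alone (median 0.32; TGFBI 2.82 ± 0.110), NF-kappaB genes in 9 of 14 against 2, 3 adjusted over the list alone (median 0.99; ICAM1 1.95 ± 0.124), basal genes in 11 of 16 against 3 (median 0.52) and cholesterol synthesis genes in 14 of 25 (15 adjusted over the list alone) against 4 (median 0.18; SREBF2 1.11 ± 0.0735). Oxidative phosphorylation genes fell in 16 of 32 cases and rose in 2 (median -0.16). These 12 lists had Benjamini-Hochberg adjusted camera p of 1.4e-07 to 0.0259; with an estimated correlation epithelial genes kept the call at adjusted p = 0.0498, while the other 11 had adjusted p = 0.0642 to 0.70. The oxidative phosphorylation call was lost without SR2211 replicate 2 or 3 (adjusted p = 0.0726 and 0.0531). The mitochondrial mRNA, ribosomal, hypoxia, Th17 and interferon lists were not called (adjusted camera p 0.112 to 0.891, medians -0.12 to 0.19).

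In all, 9257 of 15564 genes changed with SR2211, 4691 up and 4566 down, with 1048 up and 689 down at least 2-fold. Adjusted p of the 28 named genes ran from 1.6e-13 to 0.0018 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Reads outside annotated genes made up 29.8% to 39.7% of assignable reads with SR2211 and 26.3% to 30.4% with DMSO, and MALAT1 and NEAT1 together 3.26% to 5.47% and 0.874% to 1.09% of reads in genes.

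SR2211 was last compared with depletion in the libraries labelled MCF-7 and with the vector. The test of the difference, in 1 fit of 12 libraries, called 8060 of 17591 genes, 4066 higher and 3994 lower after depletion. RORC differed by -5.44 ± 0.146, since depletion lowered it and SR2211 raised it. Of 4979 genes called in both, 59.0% moved the same way (2937, with 2273 by chance; r = 0.129 across genes). GDF15 (2.06 and 3.91), NUPR1 (0.84 and 4.31), DDIT4 (2.13 and 2.96) and DDIT3 (1.21 and 3.78) rose after siRNA and with SR2211, and TMEM64 (-2.97 and -1.47), FAM111B (-1.43 and -3.0), the cyclin CCNE2 (-1.43 and -2.34) and PCNA (-1.89 and -1.73) fell in both. AREG (1.80 and -1.55) and the receptor NPY1R (0.90 and -2.28) rose after siRNA and fell with SR2211, while SCD (-1.13 and 2.82), the clock gene PER1 (-0.93 and 2.80) and ACSL1 (-0.33 and 2.91) did the reverse. The other depletions resembled SR2211 to a like degree, with 60.4% of 5833 shared calls the same way in T-47D and 61.2% of 5150 in MDA-MB-231. The RORC vector ran against SR2211, with 2094 of 2420 shared calls opposite (987 by chance) and 13.5% the same way (r = -0.298). GDF15 (-2.14 and 3.91), NEAT1 (-1.09 and 4.04), DDIT3 (-0.45 and 3.78) and DDIT4 (-1.25 and 2.96) fell with the vector and rose with SR2211, and FAM111B (0.14 and -3.0) and CCNE2 (0.17 and -2.34) did the reverse. The vector calls of FAM111B and CCNE2 were lost without empty vector replicate 1 (edgeR, Benjamini-Hochberg adjusted p = 0.0508 and 0.0615), and that of CCNE2 also without RORC vector replicate 1 or 3 (0.14 and 0.0750). Both, with NEAT1, were lost in 1 fit of all 30 libraries. The vector also ran against depletion in the other lines, with 30.1% of 1994 shared calls the same way for the libraries labelled MCF-7 and 32.1% of 2300 for T-47D. At changes of at least 2-fold the former overlap turned to 1.35 times chance, from 0.69, on 2 genes, or 18.2% of the shared calls. The luminal, vector and SR2211 comparisons came from different lines or experiments, so shared and opposite calls also carry the differences between those experiments. Read shares also ran opposite ways. Reads outside genes made up 12.6% to 13.5% of assignable reads with the RORC vector against 14.7% to 19.9% with the empty vector. With SR2211 they made up 29.8% to 39.7% against 26.3% to 30.4% with DMSO. Mitochondrial ribosomal RNA was at most 0.04046% with the RORC vector and at least 0.05185% with the empty vector. It was at least 0.09932% with SR2211 and at most 0.08091% with DMSO. Whether this carried opposite calls was not tested.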

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

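The tests of seed carriers as the whole of the shared response, of a cell line other than the label, of a difference in experiment or library preparation, and of leaving out MALAT1 and NEAT1 were chosen only after the results were seen, and the other tests were set before.

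Depletion moved many genes the same way in lines whose RORC level differed 75.7-fold, and 3 explanations were weighed: unintended targets through the seed of the siRNA guide, genes that carry the presumed seed word as the whole of the response, and loss of the RORC transcript. A seed effect was predicted to make carriers of the same or overlapping 3′ UTR words fall most in all 3 lines. The shared word was to have a strongly negative z in MDA-MB-231 but not with the vector or SR2211. GCTTCTA was the lowest of 16383 words in each siRNA set (z = -10.3 and -9.61 in the luminal sets and -14.0 in MDA-MB-231), against z = 0.561 with the vector and -0.377 with SR2211. Words whose carriers rose reached z of 8.59 and 7.57 in the luminal sets and 10.5 in MDA-MB-231, so scores near this size were not limited to falls. The word was found from the fold changes alone and could not be checked against the siRNA, whose sequence is not given. Joined with its overlapping neighbours it reads GAGCTTCTATAG, found in 3 of 4 RORC transcripts. Of 1970 genes that fell in all 3 lines 18.4% carried GCTTCTA (CBFB, DCP2 and PCNA among them), against 9.98% of 11050 genes. This share is no separate support, since the word was chosen by the falls of its carriers. An unintended effect is a candidate explanation for carriers. Carriers were not the whole of the response: without them the correlation of T-47D and MDA-MB-231 changes was 0.478 against 0.499, OIP5, TMEM64 and E2F7 carry no such word, and only 2 of 33 DNA replication genes do. Carriers here are genes with GCTTCTA in the 3′ UTR. Overlapping words such as CTTCTAT (z = -10.1 and -8.43 in the luminal sets and -13.3 in MDA-MB-231) were not counted. Sites outside 3′ UTRs and genes downstream of carriers were not counted either, so an unintended effect beyond carriers was not excluded. The test of RORC loss could not decide, since changes in MDA-MB-231, which had little RORC to lose, had a slope of 0.516 on those in T-47D over 4016 genes chosen as called the same way in all 3 lines, a choice that can raise the slope, while 63.8% of 3889 shared genes moved the other way with the RORC vector.

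The siRNA libraries labelled MCF-7 resembled T-47D rather than MCF-7 with DMSO, and a cell line other than the label was weighed against a difference of experiment or library preparation. MTAP, CDKN2A, PPM1D and BCAS3, which are deleted or amplified in MCF-7, stood at least 3.81 log2 units from the DMSO libraries, and 0 of 9984 expressed protein-coding genes lay over 16-fold from T-47D in the control libraries by ratio of mean CPM (Pearson r = 0.989 across genes). Between these libraries and DMSO 4.72% of genes lay that far apart, against 1.32% between the MDA-MB-231 controls of the siRNA and vector experiments, so a change of experiment did not reach that size where it could be measured. The values are in line with T-47D or a close relative in place of MCF-7, which would make the luminal depletions 2 experiments in 1 line. No DNA was available to settle it, and no biological explanation was tested.

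SR2211 libraries held 29.8% to 39.7% of assignable reads outside annotated genes, a signal in reads that no comparison used. Replicates 2 and 3 (39.7% and 39.0%) lay above the 30.4% of the highest DMSO library, and replicate 1 (29.8%) did not. Whether that share carried the gene changes was tested on SR2211 replicate 1 and DMSO replicate 3, whose shares were nearly equal, and their changes had a slope of 0.758 on those of the other 4 libraries. This test could not decide, since the pair is 1 library against 1 and its genes were called with the pair included. SR2211 replicate 1 also differed more from replicates 2 and 3 (chi-square per degree of freedom 12.1 and 14.1) than those did from each other (2.51). A shift of the scaling by abundant nuclear RNA was tested by leaving out MALAT1 and NEAT1. This gave 9244 called genes, 9125 of them among the 9257 called before, and a median change of -0.01. TMM trims genes of extreme change or level, so leaving these genes out could hardly move the scaling. The test covers MALAT1 and NEAT1 only and could not decide about nuclear RNA as a whole. An effect of the higher share on the gene changes and a response to SR2211 cannot be told apart here.

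Other groupings of the same libraries were tried for each count of called genes. For the 5 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05: in each the real split was the 1 of 10 with the most calls, and edgeR called 0 genes in every other. Every other split put treated and control libraries into both groups, which widens their spread, so few calls were likely there from the start. In the joint fits, the real grouping was the 1 of 100 with the most calls for the mean over 3 lines (highest other 4393), for libraries labelled MCF-7 minus MDA-MB-231 (292), for T-47D minus MDA-MB-231 (4499) and for depletion minus SR2211 (3765). For libraries labelled MCF-7 minus T-47D, 3 of 100 groupings called as many genes, the real one included, and the highest other called 6101. Labels were exchanged within each siRNA set or experiment, so another grouping could still hold a whole treatment effect. The grouping with 6101 kept all T-47D labels, and those with 4393 and 4499 exchanged all of them. These counts are thus not chance levels, and the groupings could not decide whether responses differed.

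Tests of a difference between siRNA sets in response to RORC siRNA singled out 1672 genes between libraries labelled MCF-7 and T-47D, 5059 between those labelled MCF-7 and MDA-MB-231 and 7015 between T-47D and MDA-MB-231. The same kind of test between depletion and SR2211 singled out 8060 genes. Between libraries labelled MCF-7 and T-47D the tested differences were furthest in CREB3L1 (2.45, from 7 to 23 reads per group), GRK5 (2.06), SGK1 (1.71) and STC1 (1.63), and in UNC5B (-2.29), GDF15 (-2.01), S100P (-1.89) and LAMP3 (-1.79). Relative to MDA-MB-231 the libraries labelled MCF-7 differed in RORC (-1.21), GPR158 (2.84), SLC7A2 (2.79, with 5 reads in the control group labelled MCF-7) and MT-RNR1 (6.51). The MT-RNR1 difference was 0.07 without RORC siRNA replicate 2 labelled MCF-7 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.92). T-47D differed from MDA-MB-231 in RORC by -1.31. Depletion and SR2211 differed in RORC (-5.44), CXCR4 (4.31), S100P (-4.66), NEAT1 (-4.18) and SCD (-3.95), each singled out by the test of the difference. RORC siRNA replicate 2 labelled MCF-7 held 86.7 M alignments that were not unique, against 8.95 M to 36.2 M in the other libraries, a signal in a count that no comparison used.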

How the results depend on the processing

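The tests without MALAT1 and NEAT1 and of the mean over T-47D and MDA-MB-231 only (10186 genes called) were chosen only after the results were seen. Of 6827 values of named genes under an alternative, 6631 kept direction and call, 191 lost the call, 5 gained it and 0 reversed, by edgeR or DESeq2; of 822 values of called lists, 747 kept and 75 lost the call. Each fall or rise of RORC kept its call, though its differences from MDA-MB-231 did not without some libraries. RLE size factors, no filter, the stricter filter and DESeq2 kept every count of called genes within 1.5 times the main count, as did 1 fit of all 30 libraries in the 5 comparisons it was run for. Which direction held more calls turned under at least 1 setting in every test but T-47D minus MDA-MB-231. With an estimated correlation, 5 of 10 lists stayed called for the libraries labelled MCF-7, 2 of 11 for T-47D, 0 of 10 for MDA-MB-231 siRNA, 0 of 18 for the vector and 7 of 18 for SR2211 by camera; the cause was not tested. Fry, which compares a list with no other genes, called 18 in either luminal siRNA set. At changes of at least 2-fold, shared calls stood at 13.9 times chance (libraries labelled MCF-7 with T-47D), 14.8 (with MDA-MB-231 siRNA), 3.73 (with SR2211) and 1.35 (with the vector, where it turned from 0.69 on 2 genes); the cause was not tested beyond the fewer genes. The same threshold gave 9.21 for T-47D with MDA-MB-231 siRNA, 3.47 for T-47D with SR2211, 2.50 for MDA-MB-231 siRNA with SR2211, 0.729 for the vector with SR2211 (1 gene) and 3.57 for MDA-MB-231 siRNA opposite to the vector (3 genes, while 62.5% of shared calls moved the same way). RORC in T-47D controls was 49.1 CPM with library totals only; TMM factors by construction set the difference from 46.2. Leaving out each library in turn gave 2103 to 3582 called genes for the vector against 3634; the lowest was without empty vector replicate 1, and the cause was not tested. Other ranges were 7169 to 7943 (libraries labelled MCF-7), 9062 to 10198 (T-47D), 8020 to 9690 (MDA-MB-231 siRNA), 8121 to 10356 (SR2211), 10695 to 10971 (mean over lines), 1211 to 1861, 4435 to 5369 and 6427 to 7221 (differences between lines) and 7498 to 8634 (depletion minus SR2211). With replicate number as a block, 7866, 9743, 8721, 5067 and 9994 genes were called in the 5 comparisons and 1318 between libraries labelled MCF-7 and T-47D; same-numbered libraries correlated at r = -0.0836 to 0.198, and 9 of 30 correlated best with their own number: 5 of 6 for SR2211 and 4 of 6 for the vector, where the block raised the count, and 0 of 18 in the siRNA sets. In no comparison did every pair pass r = 0.1, so the numbers were not taken as pairs. Depth limits RORC in MDA-MB-231, with 5 to 9 reads after siRNA. In simulation with 200 genes changed, 70.1% of 1.5-fold changes were found for the libraries labelled MCF-7 and 85.1% for T-47D. Depth was not told apart from the spread between replicates there.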

Other observations

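No tests in this part were made to explain a result, and its genes, apart from those of the overlaps, were chosen after their values were seen. The relatives of RORC moved less than RORC did. RORB rose after RORC siRNA in MDA-MB-231 (0.99 ± 0.185, from 0.519 to 1.03 CPM) and in the libraries labelled MCF-7 (0.41 ± 0.102), but was not called in T-47D (0.07 ± 0.0868). RORA fell after siRNA in MDA-MB-231 (-0.49 ± 0.190). The RORC vector lowered both RORA (-0.45 ± 0.0807) and RORB (-0.61 ± 0.182) in MDA-MB-231. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment these 6 changes had adjusted p of 0.00043, 0.0012, 0.49, 0.046, 0.00048 and 0.020. The RORA call after siRNA was lost with DESeq2 and without any single library but RORC siRNA replicate 3 (edgeR, Benjamini-Hochberg adjusted p = 0.0705 to 0.16), and that of RORB with the vector was lost with DESeq2 and without empty vector or RORC vector replicate 1. The ribosomal protein gene RPS8 fell in all 3 lines after siRNA (-0.62 ± 0.0508 for the libraries labelled MCF-7, -0.63 ± 0.0547 for T-47D and -0.82 ± 0.0268 for MDA-MB-231), although ribosomal genes as a list were not called there. HMOX1 (1.75 ± 0.0668) and the endoplasmic reticulum gene SEL1L (1.27 ± 0.0471) rose and the cytokine receptor IL17RB (-1.06 ± 0.0778) fell in the libraries labelled MCF-7. In T-47D the p53 target TP53INP1 rose by 1.5 ± 0.0630 and the adhesion molecule ICAM1 by 2.05 ± 0.152. MDA-MB-231 lost the glucose transporter SLC2A1 (-1.19 ± 0.0263), the cytokine IL11 (-1.20 ± 0.0378) and lymphotoxin beta (LTB, -2.19 ± 0.259) and gained the receptor PDGFRB (1.20 ± 0.0579). SR2211 raised VEGFA (1.58 ± 0.0560) and the transcription factor BATF (1.39 ± 0.0788) in MCF-7, and KLF4 fell with the RORC vector (-0.57 ± 0.0470) and rose with SR2211 (1.90 ± 0.0966).

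Some genes moved the same way when RORC was depleted and when it was supplied. The inhibitor ID1 (1.30 and 1.67 in the luminal sets, 0.29 with the vector), ID3 (1.71, 1.41 and 0.30), the tubulin TUBB3 (1.92, 2.28 and 0.37) and the survival factor MCL1 (1.52, 1.83 and 0.11) rose in each. E2F7 (-2.47, -3.16 and -0.13) and the desmosomal cadherin DSG2 (-1.64, -2.20 and -0.17) fell in each. The vector call of MCL1 was lost without empty vector or RORC vector replicate 3, that of E2F7 without empty vector replicate 1 and that of DSG2 without empty vector replicate 1 or RORC vector replicate 1 or 3. Between the luminal sets few genes turned: the collagen COL12A1 (0.27 and -0.91) and the corepressor HR (0.66 and -0.40) rose in the libraries labelled MCF-7 and fell in T-47D, and TXNIP (-0.39 and 0.47) and CREBRF (-0.40 and 0.34) did the reverse.

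RORC siRNA replicate 2 labelled MCF-7 held 271999 reads of MT-RNR1 and 306739 of MT-RNR2. Empty vector replicate 2 held 0.314% of its reads in these genes.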
